A study of Mus musculus with 6 samples.

How the data were processed

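Total RNA from snap-frozen liver of 3 control and 3 Dhx32 homozygous mutant male mice was amplified, labelled with biotin and hybridised to Affymetrix exon arrays, per the labels' protocols. These arrays carry 1 or more probe sets for most exons of a gene. The deposited values are log2 signals, 1 for each of 204531 probe sets on each of 6 arrays. Affymetrix Expression Console 1.1, RMA, Partek 6.4 and the mouse build mm9 are named in the submitters' processing notes, without saying which step each served. RMA subtracts background, normalizes arrays to each other by quantiles and summarises the probes of a probe set. It draws array-wide differences together and compresses differences of dim probe sets. Array medians still differed slightly (6.73 to 6.95). The series' design text states that signals under 3 were left out of the authors' splicing p-values; values under 3 were present in the deposited table, down to 0.36.

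Gene names came from the platform annotation, which gives symbols only. Of the probe sets, 185264 had 1 gene symbol, 3488 had several and 15779 were not listed. The 16139 single symbols were checked against a current RefSeq gene table: 13995 were current, 2104 were replaced through a unique synonym and 40 were not matched. The assembly of that table differs from mm9, so it served only for names, chromosomes and the order of neighbouring genes, and no coordinates are printed. Tedc2 and Zfp874a carry older clone names in the annotation. Probe sets with several genes or none were not named. A test on the 16953 of them above the signal minimum called 0 in limma, with 921 at an unadjusted p under 0.05.

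A probe set was kept where the mean log2 signal of a group was 3 or more, which kept 191663 and left out 12868. A gene's value was the mean over its kept probe sets, with at least 2 (15045 genes). Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, mutant minus control, with Benjamini-Hochberg adjustment over all genes or probe sets tested and a threshold of 0.05. Exon usage was tested with the diffSplice F-test of limma in the 14310 genes with at least 3 kept probe sets. The authors' own splicing algorithm, in Partek, was not used here. A set of 43 gene lists (liver pathways, zonation, sex-biased genes, markers of other cell types, RNA quality and handling genes, the helicase family and the neighbours of Dhx32) was tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry. Members were also counted after adjustment over the list alone. With 3 arrays per group, adjusted p-values come from limma, which shares information on the spread across genes. Labels number the mice within each group.

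Genes were named by a fixed rule. It took Dhx32 with its probe sets, the 10 genes with the largest rise and the 10 with the largest fall past the threshold, or the 5 of smallest p in a direction where fewer than 5 passed, the 10 genes of smallest p for exon usage, and up to 4 members of smallest p from each list described. Predicted genes were passed over. The samples' groups, tests, lists, naming rule and most alternatives were set before the data were examined. The alternatives were other signal minimums (none and 5), quantile normalization, median centring, moderation with a trend or without eBayes, array weights, a replicate block, other exon usage tests and leaving out each array. Added after seeing the data were an exon usage test with each probe set's own variance, a fit with a clock covariate, and every explanation test except the counts over other splits of the arrays.

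The steps were tested on simulated data with the real genes and the spread of each, made equal on all arrays. Of genes shifted by 0.5, 1 and 2 log2 units, the gene-level step over 15045 genes recovered 2.99%, 37.3% and 93.9%, with 4 false calls, so shifts of 0.5 in single genes are mostly missed at this number of arrays. For exon usage over 14310 genes, with 1 probe set lowered by 1, 2 or 3 log2 units, the F-test recovered 1.49%, 23.9% and 77.3% with 37 false calls. The test with own variances recovered 0%, 2.99% and 65.2% with 1 false call. In 10 further simulated sets with no change the F-test called 14 to 31 genes.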

Results

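RNA from the livers of 6 adult male mice, 6 to 8 weeks old, was hybridised to exon-level arrays, 1 array per mouse. The labels assign 3 mice to the control group and 3 to a group homozygous for a mutation of Dhx32, a gene of the DEAH-box family of RNA helicases, several of which act in splicing. The study asked which transcripts, and which exons within transcripts, differ in liver when Dhx32 is mutated. Each array held log2 signals for 204531 probe sets, with medians of 6.73 to 6.95 across the arrays. Between 7.90% and 8.28% of the probe sets lay under a log2 signal of 3 on an array. Arrays carry no read depth, so their number, 3 per group, limits the precision. Mutant replicate 1 stood apart: its correlations with the other arrays ran from 0.935 to 0.940, whereas those among the other 5 reached 0.973. Fold values below are powers of 2 of differences between group means of log2 signal.

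Dhx32 transcript was lower in every mutant liver. The mean over its 16 measured probe sets was 8.58 ± 0.29 (SD, n = 3) on the log2 scale in controls and 6.66 ± 0.35 (SD, n = 3) in mutants, which is 3.78-fold lower. The lowest control (8.28) lay above the highest mutant (7.04). The change was unequal along the transcript. In 7 probe sets the signal fell by 2.12 to 5.26, with a mean of -3.52, whereas the other 9 had differences of -1.04 to -0.26, with a mean of -0.68. Probe set 4537138 went from 8.94 ± 0.45 to 3.69 ± 0.89 (SD, n = 3), with mutant replicate 1 (2.67) under the signal minimum of 3, so the size of its fall is limited by the background. Probe set 5396990 went from 7.15 ± 0.53 to 2.68 ± 0.26, also under that minimum. At the other end, probe set 4882961 read 8.02 ± 0.18 in controls and 7.75 ± 0.19 in mutants, so this part of the transcript remained well detected. After adjustment over the 16 probe sets of the gene, 11 were lower in mutants at the 0.05 threshold in limma. In 11 of the 16 the groups did not overlap, with the mutants lower. Chance gives no overlap, in either direction, in 10% of comparisons of 3 against 3. These probe sets share the same mice, so they are not separate comparisons. For the gene as a whole limma gave an unadjusted p = 2.43e-05 and an adjusted p = 0.183 over 15045 genes, and the smallest p an exact two-sided permutation test allows here is 0.1. The nature of the mutation is not given in the sources used here, and the positions of these probe sets within the gene were not analysed here.

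**Figure D1:**
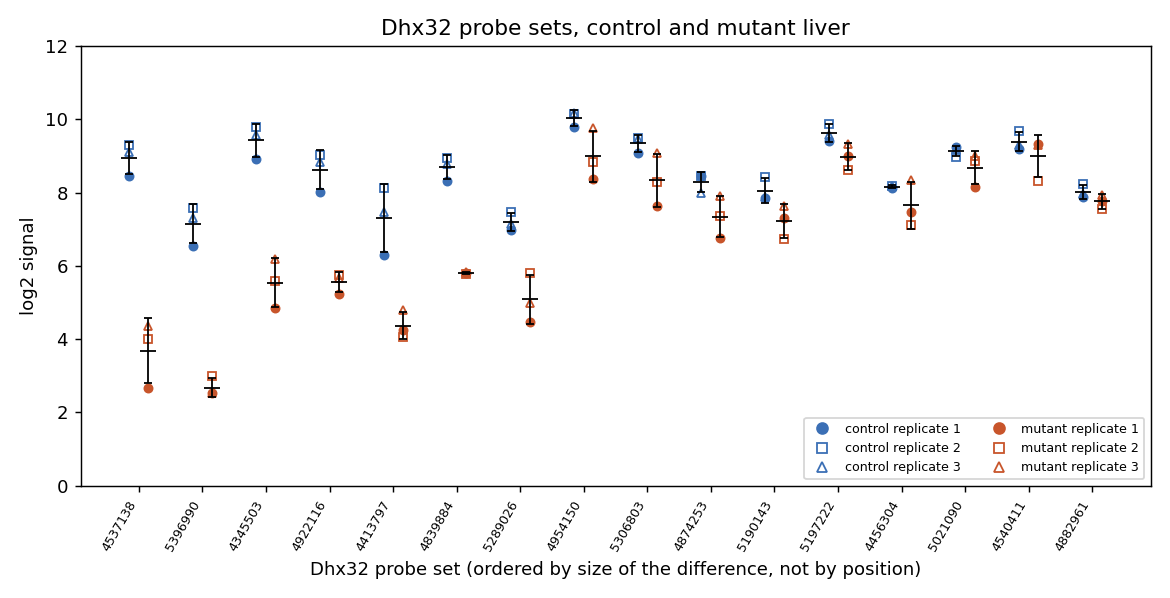
Log2 signal of each of the 16 measured Dhx32 probe sets on the 3 control arrays (blue) and the 3 mutant arrays (orange), with the group mean (black bar) and SD (error bar); probe sets are ordered by the size of the difference, not by position in the gene. The 7 probe sets on the left lost 2.12 to 5.26 log2 units in mutants, the 9 on the right lay 0.26 to 1.04 lower.

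None of the genes surrounding Dhx32 on chromosome 7 passed. Bccip and Uros, the nearest measured genes on one side, differed by -0.09 (SE 0.21) and 0.15 (SE 0.21), and Fank1 on the other side by 0.20 (SE 0.16). In the list of 18 measured genes around Dhx32, none passed over all genes or when adjusted over the list alone. Nor did any of the 30 genes nearest to Dhx32, counting both sides together, pass for exon usage, where each had an adjusted p = 1. Eef1akmt2, which encodes a lysine methyltransferase of elongation factor 1A, had the smallest p of the list, with a difference of -0.67 (SE 0.24; adjusted p = 0.405 over the list alone). Other members of the helicase family did not pass either: 9 of 16 were higher and 7 lower. Dhx40 differed by -0.84 (SE 0.21; adjusted p = 0.0590 over the list alone, 0.943 over all genes in limma).

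Outside Dhx32, few single genes separated the groups. Zfp874a, a zinc finger gene on chromosome 13, was 4.79-fold lower in mutants, at 8.48 ± 0.29 (SD, n = 3) in controls and 6.22 ± 0.07 (SD, n = 3) in mutants. It was the only one of 15045 genes past the threshold in limma (adjusted p = 0.0190). Zfp874a also passed the exon usage test (adjusted p = 0.00234), with probe set 5067632 at 9.62 ± 0.76 in controls and 5.34 ± 0.55 in mutants. Aqp4, a water channel, differed by -1.27 (SE 0.21), Ttc39c by -0.89 (SE 0.15) and Tedc2 by -0.82 (SE 0.14). These 3 genes did not pass (adjusted p = 0.547), and Aqp4 and Ttc39c both lie on chromosome 18. The higher genes of smallest p, none of which passed (adjusted p = 0.547), were Mvd, Il9, Rgs13, Synj2 and Lcn2. Mvd, an enzyme of the mevalonate pathway, differed by 1.16 (SE 0.17), with 8.08 to 8.26 in the mutants against 6.76 to 7.23 in the controls. Synj2, an inositol phosphatase, differed by 0.91 (SE 0.16). Lcn2, an iron-sequestering protein of the acute phase response, had the largest difference of these, 4.32 (SE 0.76) or 20.02-fold, and stood at 13.6, 11.2 and 10.1 in the 3 mutants against 6.88 to 7.93 in the controls. Without mutant replicate 1 the Lcn2 difference was 10.2-fold. Il9 (1.07, SE 0.17) and Rgs13 (0.98, SE 0.16) were dim, with control means of 3.78 and 2.82.

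At an unadjusted p under 0.05, 633 genes differed, 302 higher and 331 lower in mutants, where 752 would be reached by chance. With 1 array left out this count ran from 323 (control replicate 2) to 1356 (mutant replicate 3), so it fell on both sides of that number. Of 191663 single probe sets, 0 passed in limma and 7805 reached an unadjusted p under 0.05, against 9583 by chance. Zfp874a lost its place past the threshold without control replicate 2, control replicate 3 or mutant replicate 1, 2 or 3, and no gene passed without control replicate 2, control replicate 3, mutant replicate 1 or mutant replicate 3. Without control replicate 1 the count was 3 genes, which were Moxd1, Sqle and Zfp874a, and without mutant replicate 2 it was 1 gene, Serpina1d; these names were taken after their values were seen.

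Genes of the unfolded protein response, which raise the folding capacity of the endoplasmic reticulum, were higher in mutant livers. Of 21 measured members 20 had a higher mean in mutants, with a median difference of 0.49, and 7 rose when adjusted over the list alone. The 4 members of smallest p were Derl3, which acts in the removal of misfolded proteins (1.40, SE 0.26), the chaperone partner Dnajb9 (1.01, SE 0.23), Sdf2l1 (1.32, SE 0.36) and the secreted stress protein Manf (0.94, SE 0.28). Averaged over the list, the 3 mutants lay 0.75, 0.45 and 0.45 above the control mean, and the highest control lay 0.11 above it. On all 6 arrays the list had the smallest p of 43 tested with camera at a preset correlation (adjusted p = 5.35e-11); without mutant replicate 1 that of cholesterol synthesis was smaller (adjusted p = 2.60e-19, against 2.57e-08; 0.368 and 0.344 with an estimated correlation). With an estimated correlation the unfolded protein response list had an adjusted p = 0.288, the smallest of any list, so the call did not hold.

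Enzymes of cholesterol synthesis were also higher, but not in all mutants. Of 20 measured members 17 had a higher mean in mutants, with a median difference of 0.50 (adjusted p = 6.02e-08 at the preset correlation, adjusted p = 0.751 with an estimated correlation). Mvd alone rose when adjusted over the list alone. Sqle, which makes squalene epoxide, differed by 2.03 (SE 0.60), but control replicate 1 (9.39) lay near the mutants (9.46 to 10.1) and far from the other controls (6.87 and 6.99). Lss differed by 0.67 (SE 0.27) and Dhcr7 by 0.51 (SE 0.20). The list's mean lay 0.84 and 0.68 above the control mean in mutant replicates 2 and 3, and 0.01 above it in mutant replicate 1.

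Acute phase genes, secreted by the liver during inflammation, were higher mainly in 1 mutant. Mutant replicate 1 lay 1.74 above the control mean over the 22 measured members, mutant replicates 2 and 3 lay 0.26 and 0.27 above it, and the controls ranged from -0.18 to 0.20. Lcn2 rose when adjusted over the list alone (adjusted p = 0.00901). Saa3, a serum amyloid A, differed by 3.29 (SE 0.97), Apcs by 2.28 (SE 0.75) and haptoglobin (Hp) by 0.92 (SE 0.29). The list passed at the preset correlation (adjusted p = 1.69e-06) and not with an estimated correlation (adjusted p = 0.751). Without mutant replicate 1 its median difference was 0.04 (adjusted p = 0.0872), and without mutant replicate 2 or 3 it was 0.67. The differences of Saa3, Apcs and Hp were 2.08, 1.57 and 0.56 without mutant replicate 1. Neutrophil and granulocyte markers had the same array highest, with mutant replicate 1 at 0.77 over 12 genes and the other mutants at 0.13 and -0.01. That list passed at the preset correlation (adjusted p = 0.0206; adjusted p = 0.751 with an estimated correlation), and not without mutant replicate 1, control replicate 1 or control replicate 2 (adjusted p = 0.897, 0.0879 and 0.124). Of the 12 genes 9 were higher and 3 lower. Prtn3, a granule protease, differed by 1.05 (SE 0.33), Ngp by 0.59 (SE 0.23, and 0.35 without mutant replicate 1) and Camp by -0.35 (SE 0.20).

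The lists called lower at the preset correlation, none of which passed with an estimated one, were metabolic. Of 21 genes of fatty acid and triglyceride synthesis 20 had a lower mean in mutants (median -0.29, adjusted p = 1.23e-04; adjusted p = 0.751 with an estimated correlation), among them the desaturase Scd1 (-0.72, SE 0.25) and the carbohydrate-response factor Mlxipl (-0.45, SE 0.16). Of 26 genes of xenobiotic metabolism 22 were lower (median -0.25, adjusted p = 2.84e-04; adjusted p = 0.751 with an estimated correlation), including Cyp2c37 (-1.69, SE 0.55), Cyp2c55 (-1.56, SE 0.48) and Gsta4 (-0.53, SE 0.19). Of 19 genes of the urea cycle and amino acid breakdown 17 were lower (median -0.24, adjusted p = 0.00189; adjusted p = 0.751 with an estimated correlation), for example Cth (-0.71, SE 0.26) and Asl (-0.50, SE 0.24). Of 15 genes of gluconeogenesis and glycogen metabolism 12 were lower (median -0.34, adjusted p = 0.0189; adjusted p = 0.751 with an estimated correlation), with Pygl at -0.51 (SE 0.22) and Ppargc1a at -1.10 (SE 0.48). No member of these 4 lists passed when adjusted over its list alone. Without mutant replicate 1 the medians were -0.13, -0.08, -0.11 and -0.20 in the order above. Fatty acid synthesis alone of the 4 then still passed in camera at the preset correlation (adjusted p = 0.0106, and for the others 0.0957, 0.0619 and 0.163). With an estimated correlation none of the 4 passed without that array (adjusted p = 0.890 for each). The gluconeogenesis call was also lost without control replicate 2, control replicate 3 or mutant replicate 2 (adjusted p = 0.0947, 0.250 and 0.0862), and the urea cycle median was -0.11 without control replicate 2. Without control replicate 1 the medians of fatty acid synthesis and gluconeogenesis were -0.48 and -0.54, and without mutant replicate 3 those of fatty acid synthesis, xenobiotic metabolism and gluconeogenesis were -0.45, -0.43 and -0.53. Scd1, Cth, Pygl and Ppargc1a differed by -0.45, -0.44, -0.30 and -0.66 without mutant replicate 1. Mutant replicate 1 was the lowest array in all of them, at -0.63, -0.78, -0.53 and -0.68 from the control mean. Mutant replicate 3, at 0.00, 0.08, -0.04 and 0.07, lay within the controls. Control replicate 1 was the lowest control, at -0.30, -0.25, -0.25 and -0.38. Mutant replicate 2, at -0.31, -0.43, -0.21 and -0.27, lay within the controls for the urea cycle and gluconeogenesis. In fatty acid synthesis it lay only just below them. The clock output factor Dbp read 6.90 and 6.91 in mutant replicates 1 and 2 and 7.29 in control replicate 1, against 8.71 to 8.93 in the other 3 livers. With the clock covariate 5 lists passed in camera at the preset correlation. Of these 5 lists, 4 had also been called without the covariate, in the same direction. Among the 5 were the unfolded protein response, cholesterol synthesis and acute phase lists (adjusted p = 6.08e-08, 2.00e-06 and 0.0203). Most of the 4 lower lists thus lost their calls.

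Of the remaining lists, 3 passed at the preset correlation, all higher in mutants. Adipocyte markers had 11 of 14 members higher (median 0.30, adjusted p = 0.0115; adjusted p = 0.639 with an estimated correlation), with Cfd at 0.91 (SE 0.39) and the dim hormone genes Lep at 0.65 (SE 0.16) and Adipoq at 0.64 (SE 0.26). Heat shock genes and chaperones had 11 of 15 higher (median 0.20, adjusted p = 0.0189; adjusted p = 0.725 with an estimated correlation), with Hsph1 at 0.63 (SE 0.24; 0.35 without mutant replicate 1) and Dnajb1 at 0.42 (SE 0.15). Cytosolic ribosomal protein genes had 21 of 30 higher (median 0.16, adjusted p = 0.0363; adjusted p = 0.751 with an estimated correlation), with Rpl8 at 0.48 (SE 0.17). No member of these 3 lists passed over all genes or when adjusted over its list alone. Without mutant replicate 1 the heat shock and ribosomal protein medians were 0.09 and 0.09 and neither list passed (adjusted p = 0.155 and 0.392), nor did they without control replicate 2 (medians 0.12 and 0.05, adjusted p = 0.0793 and 0.220) or mutant replicate 2 (adjusted p = 0.116 and 0.0920). The adipocyte call was lost without mutant replicate 2 (adjusted p = 0.0862), its median was 0.18 without control replicate 2 or 3, and the heat shock median was 0.31 without mutant replicate 3. The core spliceosome and splicing regulators, a list bearing on the helicase's family, had 19 of 47 members higher and 28 lower (median -0.08, adjusted p = 0.643). Its member of smallest p was Prpf31, at 0.44 (SE 0.19; adjusted p = 0.872 over the list alone).

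Altogether 7 lists were higher and 4 lower at the preset correlation, 0 of 43 with an estimated correlation, and 1 with fry, that of intestine and gallbladder epithelium (adjusted p = 0.0363; in camera 0.282). The count was 6 without mutant replicate 1, of which 4 were among the 11 in the same direction, 7 without control replicate 2 and 19 without mutant replicate 3.

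**Figure D2:**
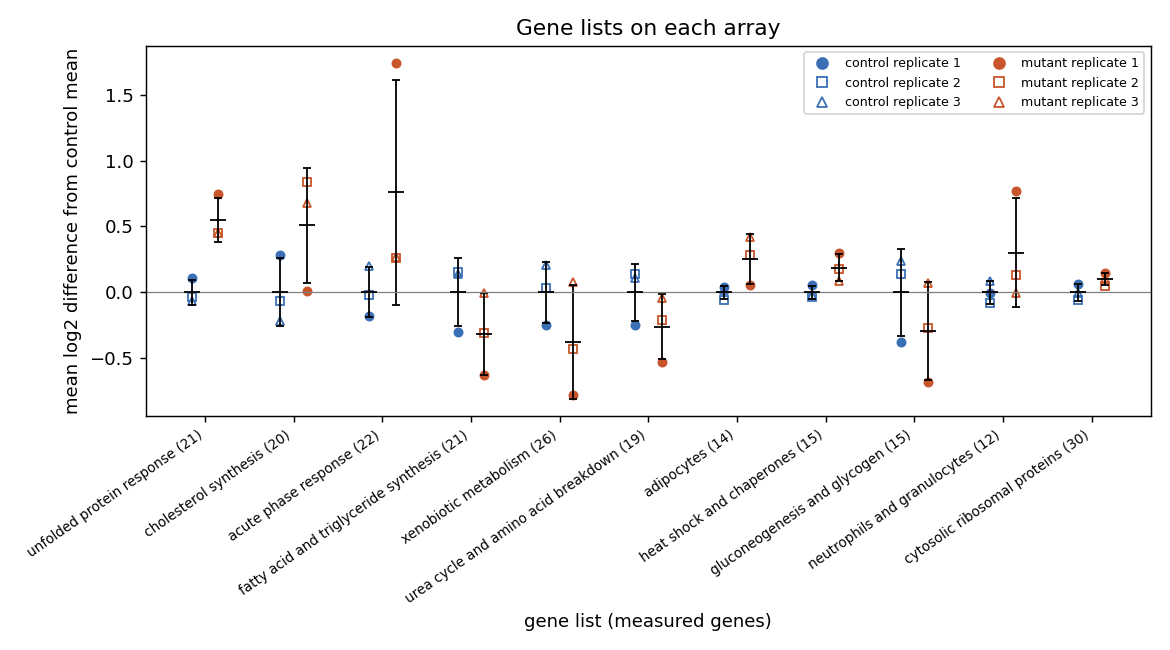
Mean log2 difference from the control mean on each array for the 11 gene lists past the threshold at the preset correlation, with group means (black bars) and SDs (error bars) over 3 control arrays (blue) and 3 mutant arrays (orange); the number of measured genes follows each list's name. Mutant replicate 1 (filled orange circle) reached 1.74 in the acute phase list. All 3 mutants lay above the controls in the unfolded protein response list, and by less in the acute phase, adipocyte and heat shock lists.

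Exon usage is the change of a probe set relative to the rest of its gene. The F-test of diffSplice gave Dhx32 itself the smallest p of 14310 genes (adjusted p = 2.01e-14), with probe set 4537138 deviating most within the gene. Wdtc1, a WD-repeat gene on chromosome 4, followed (adjusted p = 4.51e-11). Its probe set 5282845 fell from 9.70 ± 0.58 in controls to 3.25 ± 1.69 in mutants (SD, n = 3). In 6 more of the 10 genes of smallest p the most deviating probe set likewise read 7 or more in controls and far less in mutants. The probe set of Rpain, a nuclear importer of replication protein A, went from 7.10 ± 0.30 to 2.65 ± 0.54 (adjusted p = 6.07e-08). That of Pafah1b1, a regulator of dynein, went from 7.15 ± 0.34 to 2.65 ± 1.61 (adjusted p = 2.17e-08). That of the kinase gene Riok3 went from 8.25 ± 0.31 to 3.50 ± 1.71 (adjusted p = 6.99e-08). The kinesin gene Kif5b went from 7.01 ± 0.27 to 3.46 ± 1.20 (adjusted p = 1.83e-07). Ccny, which encodes cyclin Y, went from 7.001 ± 0.49 to 2.67 ± 1.49 (adjusted p = 1.96e-07), and the F-box gene Fbxo42 from 7.87 ± 0.27 to 5.61 ± 0.26 (adjusted p = 1.64e-04). The gene means of Kif5b and Fbxo42 differed by only 0.02 (SE 0.17) and -0.12 (SE 0.17).

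In the other 2 of the 10, the difference of the most deviating probe set lay above that of the gene's mean. In Aqp4 (adjusted p = 8.44e-06) the gene's mean differed by -1.27, while probe set 4425576 read 5.48 ± 1.17 in controls and 6.08 ± 0.59 in mutants. In Tiam2, an activator of Rac (adjusted p = 2.52e-09), the gene's mean differed by -1.14 (SE 0.29), while probe set 4793739 read 2.22 ± 0.95 and 3.73 ± 0.33, both near the signal minimum. Altogether 30 genes passed and 573 reached an unadjusted p under 0.05. In 23 of the 30 the most deviating probe set was lower in mutants, in 7 it was higher. Chromosomes 13 and 18 each held 6 of the 30, where 1.07 and 0.74 would be expected from the genes tested on them.

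The F-test pools the variance of a gene's probe sets, and data simulated with no change gave 14 to 31 called genes per set, so that Dhx32 and Wdtc1 alone had a p below the smallest of those sets. With its own variance for each probe set in limma, 0 genes passed (smallest adjusted p = 0.606, with 6964 of 172428 probe sets at an unadjusted p under 0.05). That test missed Dhx32, the mutated gene, too (adjusted p = 0.606 for probe set 4537138), so its 0 calls cannot decide on the other genes. The F-test count was 13 genes without control replicate 2, 17 without control replicate 3 and 58 without mutant replicate 2.

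**Figure D3:**
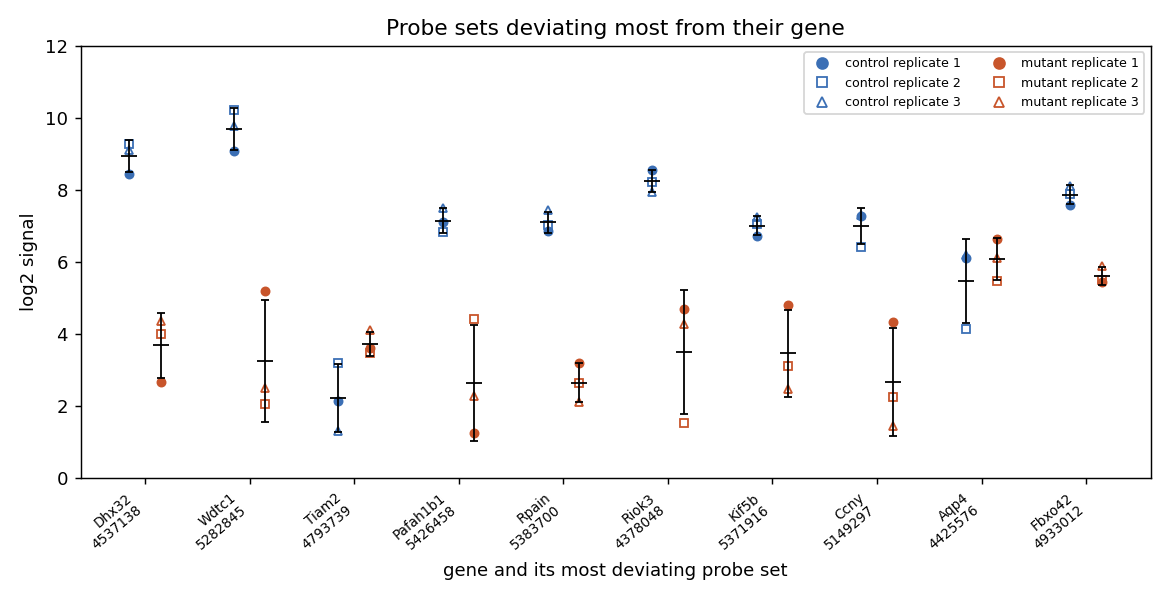
Log2 signal of the most deviating probe set in the 10 genes of smallest exon usage p, on the 3 control arrays (blue) and 3 mutant arrays (orange), with group means (black bars) and SDs (error bars). In 8 of the 10 genes the mutant signals lay below those of the controls; in Tiam2 and Aqp4 the mutant mean lay above.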

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

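The own-variance exon usage test and the clock covariate were chosen after seeing the data. Dhx32 was lower with an unadjusted p under 0.05 in 17 of 17 alternatives (-2.11 to -1.48; p from 3.63e-06 to 3.51e-04 in limma), and its adjusted p over all genes passed in 3 of 17. Zfp874a passed in 9 of 17 (adjusted p 0.00505 to 0.264). The unfolded protein response and cholesterol synthesis lists passed at the preset correlation in 17 of 17 (adjusted p up to 6.08e-08 and 0.00539), and neither passed with an estimated one (adjusted p = 0.288 and 0.751). Gene-level calls, 1 as reported, were 0 with no signal minimum, without eBayes and with the clock covariate (510 at an unadjusted p under 0.05 with that covariate in limma), 2 with quantile normalization, median centring or array weights, and 0 to 3 when 1 array was left out. Probe-set calls, 0 as reported, were 2 with a minimum of 5, 9 with a trended robust eBayes, 3 with array weights and 0 to 5 with 1 array left out. Exon usage calls, 30 as reported, were 53 with an interaction model (27 shared; 50 to 72 in simulated data with no change), 130 with Simes adjustment, 0 with own variances, 17 with the clock covariate (15 shared) and 13 to 58 with 1 array left out. List calls, 11 as reported, were 0 with an estimated correlation, 1 with fry, 5 with the clock covariate (4 shared in direction) and 6 to 19 with 1 array left out. The neutrophil list reversed to a median of -0.00048 without mutant replicate 1 (up to 0.31 with another array left out), and Ltf to -0.067 with a minimum of 5. The cause of these changes was not tested, and leaving out an array also makes the number of arrays smaller. Quantile normalization and median centring moved the median of all genes by 0.03 and 0.05 log2 units. Arrays with a shared replicate number deviated with correlations of 0.10, -0.11 and 0.18. These values cannot tell whether the number pairs the arrays, since each deviation is from a mean of only 3. The arrays were treated as unpaired. With a replicate block the gene-level calls were 0 and the exon usage calls 18, of which 17 were among the 30. Signals under 3 lie at the background, which limits the size of any measured fall.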

Other observations

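All explanation tests in this part were chosen after the results were seen, except the counts over other splits of the arrays. Several genes of lists that did not pass had differences of note in single members, none of them past the threshold over all genes. Irf1, a transcription factor induced by interferon, was the only member of the 30 interferon response genes to fall when adjusted over the list alone (-0.80, SE 0.17; adjusted p = 0.0375), while Igtp, another interferon-induced gene, differed by 0.52 (SE 0.15) and the list as a whole did not pass (adjusted p = 0.960). Alas1, the first enzyme of haem synthesis, differed by 1.43 (SE 0.38; adjusted p = 0.114 over its list alone) and Cebpa, a factor of hepatocyte identity, by -0.57 (SE 0.16; adjusted p = 0.144 over its list alone). Markers of hepatocyte identity as a list had 9 members higher and 9 lower (adjusted p = 0.923). Stellate cell and fibroblast markers had 14 of 18 members lower (median -0.14, adjusted p = 0.0597), with Dcn at -0.81 (SE 0.34) and Reln at -0.93 (SE 0.40), and mutant replicate 1 lowest at -0.46; without it the median was -0.06, Dcn stood at -0.39 and Reln at -0.45. Kupffer cell and macrophage markers stood at 0.55 in mutant replicate 1 and at -0.26 and -0.25 in mutant replicates 2 and 3. Their list had an adjusted p = 0.923 over all arrays and passed as lower without mutant replicate 1 (adjusted p = 7.64e-06 at the preset correlation, adjusted p = 0.696 with an estimated correlation). Over 13491 genes, the deviations of a gene's probe sets, divided into 2 parts, correlated at 0.64 in mutant replicate 1 and at 0.43 to 0.50 in the other arrays.

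The 30 genes called for exon usage lay unevenly in the genome: 12 were on chromosomes 13 and 18, where 1.82 would be expected (permutation p = 1e-05 over all chromosomes, the smallest that the 100000 random sets can give), while among the 9 other splits of the arrays the lowest such p was 0.0315. Of the 30, 14 had another called gene within 50 tested genes, with a median of 6 in random sets (permutation p = 0.0041; 0.0062 within 25 and 0.108 within 100), and the largest cluster held Kif5b, Ccny, Usp14, Riok3, Impact and Aqp4; of the genes of smallest gene-level p, 198 of them placed, 149 had such a neighbour with a median of 142 in random sets (permutation p = 0.175), but they too lay unevenly over the chromosomes (permutation p = 0.00748), with 18 on chromosome 13 where 7.10 would be expected and 8 on chromosome 18 where 5.03 would be. The clustering and the chromosome counts argue against false calls of the F-test as the whole account of these genes. The clustering had a permutation p = 0.0041, although among the 9 other splits 1 reached 0.0370 with 4 of its 11 calls, and another 0.0849. The 15 calls outside the clusters other than Dhx32 lie within the 14 to 25 calls outside clusters in simulated data with no change. That range may not match these arrays. The simulated arrays all had the same spread, whereas mutant replicate 1 deviated more within genes (median absolute deviation 0.44, against 0.25 to 0.28). The other splits of the real arrays called 2 to 264 genes. Whether the mutants and controls carry segments of different strains, whose sequence differences under the probes may lower single probe sets, stays open, since 0 of the 30 genes around Dhx32, where a carried segment is likeliest, were called, against 6 within 33 tested genes in the largest cluster. In 13 of the 14 clustered genes and 10 of the other 16 the most deviating probe set was lower in mutants (Fisher's exact test, two-sided p = 0.0860). That test takes the genes as independent. The clustered genes were chosen for lying together, 6 of them in 1 cluster, and all genes come from the same mice, so its p has no plain meaning. For the 14 clustered genes, among them Zfp874a, the only gene-level call, an action of Dhx32 cannot be told apart from such segments, since no mutant with a background matched to the controls was analysed here.

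Over the unfolded protein response list all 3 mutants lay above all 3 controls, and a response to the loss of Dhx32 may be the reason, as a hypothesis found and tested on the same data. The shift did not lie in mutant replicate 1 alone, since the list's mean was 0.45 in both other mutants and 0.11 in the highest control. Without mutant replicate 1 the list passed in camera at the preset correlation (adjusted p = 2.57e-08), but not with an estimated correlation (adjusted p = 0.344). The median difference of all genes was -0.014 (median absolute deviation 0.21), against 0.49 for the list, so no shift of all genes of that size was left. RMA draws array-wide differences together beforehand, so this comparison could hardly come out otherwise. A shift that depends on the signal level was not tested. The inflammatory state that raised the acute phase list stays open, because the list's mean over mutant replicates 2 and 3 (0.45) lay between those of the controls and of mutant replicate 1 (0.75). With the clock covariate the list kept an adjusted p = 6.08e-08 at the preset correlation and had 0.790 with an estimated correlation.

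With 10 splits of the 6 arrays into 3 and 3, no share under 0.05 can be reached. Gene-level calls were 1 in the real split and 4 in the highest other, and 4 of the 10 splits gave as many. Probe-set calls were 0 and 11, reached by 10 of 10. Exon usage calls were 30 and 264, reached by 4 of 10, and list calls were 11 and 17, reached by 2 of 10.

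The split with control replicate 1, mutant replicate 1 and mutant replicate 2 on one side gave those 264 exon usage calls and 17 lists, with 2340 genes at an unadjusted p under 0.05 in limma against 633 in the real split, which points to a structure of the samples other than genotype. In these 3 livers the 12 measured clock genes driven through E-boxes lay -0.31, -0.71 and -0.59 from the mean of all arrays, and Nr1d1 read 9.13, 7.30 and 8.14, against 10.5 to 10.9 in the other 3. A candidate explanation is the time of day at which each liver was taken, since the mean of 5 clock genes of the opposite phase deviated the other way on 6 of 6 arrays, although single genes did so less evenly, Cry1 on 6, Nfil3 on 5, Arntl and Npas2 on 4 and Clock on 3. The same 3 arrays had the lowest median signals (6.73 to 6.81, against 6.88 to 6.95). After quantile normalization 2060 genes were left at an unadjusted p under 0.05 in limma. This argues against a shift of all genes, left in the deposited values, as the whole account. RMA had already normalized the arrays by quantiles, so this comparison could hardly come out otherwise. Fasting in some animals stays open. Fatty acid synthesis and fatty acid oxidation genes deviated in opposite directions on 0 of 6 arrays. Both lists had the sign of the E-box clock genes on 6 of 6 arrays, so this comparison cannot decide on feeding. The labels used here give no time of collection, and any role of Dhx32 in the clock was not tested apart from the circadian list, which did not pass between the groups (adjusted p = 0.0678).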
